A study of Nothobranchius furzeri with 20 samples.

How the data were processed

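The series holds RNA-seq of brain from male turquoise killifish (Nothobranchius furzeri) of the GRZ strain, in 4 age groups of 5 libraries each (5, 7, 10 and 14 weeks). Per the labels' protocols, total RNA was made into libraries with a TruSeq RNA v2 kit. The submitters' processing notes name CASAVA 1.8.2, STAR 2.4.1d and featureCounts 1.4.6-p4; the genome build, the annotation and the strand setting of the counting are not given in the sources used here. Each library was taken as 1 animal's brain; the labels list separate samples and do not say whether brains were pooled. Replicate numbers follow accession order, name a library within its age and pair nothing, so no blocked fit was made.

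The deposited count table holds raw read counts for 26739 gene identifiers in 20 libraries, with library totals of 12.004 to 30.7 M counts (M, mega). Every test of record was run on these counts. A deposited RPKM table holds the same identifiers and libraries. Its values were checked against the counts: they equal the count divided by a gene length and by a library total, but the total used is not that of the value's own library. The totals of the 20 libraries, followed by 5 totals that match no library of the count table, were applied in rotation down the rows. With that rotation 99.98% of the nonzero RPKM values of genes with an RPKM sum above 1 were given back within 0.0011, against 4.43% with each library's own total. The ratio of the deposited RPKM to one scaled by its own library's total ran from 0.379 to 2.58, with 0.617 at the 5th and 1.57 at the 95th percentile. The deposited RPKM values of a gene are therefore not comparable between libraries. They served only as an alternative, and to solve the length of 23321 genes (median 2325 bases). Of the lengths of the 21816 genes with an RPKM sum above 1, 51.8% were multiples of 3.

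The identifiers in the count table are not paired with gene names in the files, and 0 of the 26739 identifiers occur in the RefSeq gene table given for NfurGRZ-RIMD1. No gene is therefore named by symbol, and the 34 gene lists fixed beforehand were not tested. The rule for named genes, fixed before the data were examined, asked for a symbol, a mean CPM of at least 1 over the 20 libraries, an adjusted p below 0.05 and complete separation of the groups. It took the 10 largest rises and the 10 largest falls between 14 and 5 weeks, and 5 and 5 in the other comparisons. It gives no gene without symbols. The symbol condition was dropped after the identifiers were found to have no names. Then 132 rising and 201 falling identifiers qualified between 14 and 5 weeks, and only the 2 with the largest change in each direction are printed.

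Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr by age group (19474 genes kept), and a quasi-likelihood fit with robust empirical Bayes of all 20 libraries with 1 mean per age. Contrasts between ages, an F-test over the 4 ages and a slope over age in weeks were tested with Benjamini-Hochberg adjustment over all tested genes and an adjusted p below 0.05 as the threshold. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Principal components used log2 CPM (prior count 2) of the 500 most variable genes; their correlation with age was tested with 100000 permutations. The spread at an age was the mean Euclidean distance of its libraries to the group centroid in log2 CPM. Correlations across genes were set against 100 splits of the libraries compared.

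The code was tested on simulated data, with negative binomial counts drawn from the mean of each gene over all libraries, the real library totals and the estimated dispersions, and with 200 genes changed between 14 and 5 weeks. Of 19414 genes tested there, edgeR called 60 of 100 genes changed 2-fold and 89 of 100 changed 4-fold, with the right direction in each, and 5 unchanged genes. DESeq2 1.42.0 called 62 and 93, with 24 unchanged genes. Genes were drawn independently, so the simulation held no correlated genes and no libraries that stood apart. These rates test the code and need not hold for the real libraries.

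Alternatives were DESeq2 size factors, 2 other filters on low counts, DESeq2, limma-voom (limma 3.58.1), limma-trend on log2 of the deposited RPKM plus 1 or 0.1, no robust step, 1 surrogate variable (sva 3.50.0), fits of only the ages compared, other age scales and leaving out each library in turn. Added after seeing the data were leaving out the 3 libraries with the lowest median Spearman rho with the others, limma-trend on RPKM scaled by each library's own total, and correlations of differences of mean log2 CPM with every exchange of the labels. The permutation p-values of the correlations across genes without single libraries rest on that last statistic, since edgeR was not refitted for every exchange. Library pairs of 1 age were compared by a chi-square over genes with at least 20 counts in the pair; the smallest value per degree of freedom was 8.67, so no pair agreed within sampling noise. TMM and DESeq2 size factors moved the median log2 fold change of all genes by at most 0.02.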

Results

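Brain transcriptomes of male turquoise killifish of the GRZ strain were compared at 5, 7, 10 and 14 weeks of age, with 5 libraries at each age. Total counts ran from 12.004 M (M, mega) in 5-week replicate 5 to 30.7 M in 7-week replicate 4, with a median of 21.6 M. Between 21385 and 22938 of the 26739 gene identifiers had at least 1 read in a library, and 19474 genes were expressed highly enough to be tested. The files give gene identifiers without names, so groups of genes are described by their level, direction and course over age. The edgeR p-values rest on the spread between libraries within ages, estimated from all 20 libraries together and not only from the ages compared. The labels list the libraries as separate samples. Running numbers in the sample titles largely follow age, and the labels do not say what they stand for.

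The libraries did not group by age alone. Their median Spearman rho with the other 19 libraries was 0.981 at the middle of the range, and it was lowest in 7-week replicate 3 (0.925), 5-week replicate 5 (0.955) and 5-week replicate 4 (0.955). In 7-week replicate 3, 1864 genes lay more than 2-fold below the median of the other libraries of its age. The other 7-week libraries had 13 to 57 such genes. In replicate 3, 334 genes lay more than 2-fold above that median, against 13 to 95 in the others. These counts took only genes with a mean CPM of at least 8. Over all tested genes, 207 lay more than 8-fold above the group in 5-week replicate 4. PC1 held 33.1% and PC2 20.96% of the variance of the 500 most variable genes. PC1 showed no relation with age that passed the permutation test (Pearson r = 0.28, p = 0.23; Spearman rho = 0.16, p = 0.50; 20 libraries, adjusted p over both components 0.23 and 0.50). For PC2 the Spearman rho with age was 0.51 (permutation p = 0.023, adjusted p = 0.046) and Pearson's r was 0.32 (permutation p = 0.16, adjusted p = 0.23). Without 7-week replicate 3 and 5-week replicate 4, the libraries farthest out on PC2, r along the same axis was 0.18. When the components were computed anew without 7-week replicate 3, the Spearman rho with age was 0.069 for PC2 and 0.33 for PC1. The new PC2 need not be the same axis. The rho along the first PC2 without that library alone was not computed. The 10-week libraries lay closest together, at a mean distance of 38.3 ± 5.66 (SD, n = 5) from their centroid in log2 CPM. That distance was 65.2 ± 17.1 (SD, n = 5) at 5 weeks, 63.3 ± 29.2 (SD, n = 5) at 7 weeks and 51.2 ± 11.7 (SD, n = 5) at 14 weeks. The difference between 14 and 5 weeks, -14.0, was within the spread between libraries (exact permutation test of the 10 distances, two-sided, p = 0.18).

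**Figure D1:**
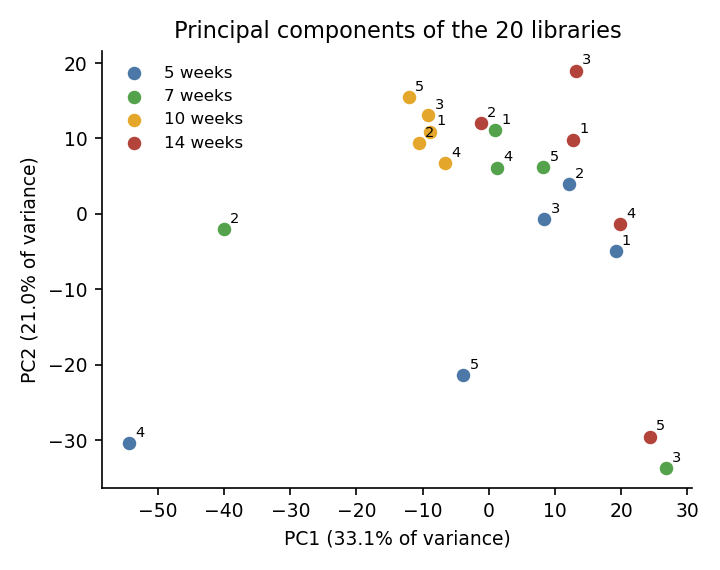
Principal components of the 20 brain libraries from log2 CPM of the 500 most variable genes, with PC1 on the horizontal and PC2 on the vertical axis. Each point is a library, coloured by age and marked with its replicate number. The 5 libraries of 10 weeks lie together, while 5-week replicate 4, 7-week replicates 2 and 3 and 14-week replicate 5 (PC2 of -29.5) lie far from the others of their age.

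The oldest and the youngest animals differed in 482 genes. At 14 weeks, 195 genes were higher and 287 lower than at 5 weeks (edgeR's quasi-likelihood test, adjusted p below 0.05), 2.5% of the genes tested. The changes were mostly moderate. The median absolute log2 fold change was 0.71 among the higher genes and 0.82 among the lower ones. At least 2-fold changes were seen in 53 higher and 104 lower genes. Falls beyond 4-fold numbered 33 and rises beyond 4-fold 3. In 348 of the 482 genes, which were chosen for differing between these libraries, all 5 libraries of 14 weeks lay on the same side of all 5 libraries of 5 weeks. Among all tested genes, called or not, 1.93% lay fully above and 3.31% fully below, where random splits give 0.397% on average in each direction. Genes vary together, so single splits can lie far from that average, and these shares were not set against other splits. Between 10 and 14 weeks, where 0 genes were called lower, 1.31% lay fully below.

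Nfu_g_1_011849 rose from 23.0 ± 7.68 CPM (SD, n = 5) at 5 weeks to 31.1 ± 15.6 at 7 weeks, 51.2 ± 28.6 at 10 weeks and 90.6 ± 44.0 at 14 weeks. Its log2 fold change between 14 and 5 weeks was 1.98 ± 0.43 (SE), with an edgeR adjusted p of 0.029, and its 14-week libraries, at 41.3 to 147.2 CPM, all lay above the 5-week libraries. Nfu_g_1_019685 was at 20.0 ± 6.77 CPM at 5 weeks, 20.7 ± 8.33 at 7 weeks, 36.5 ± 17.7 at 10 weeks and 76.2 ± 35.08 at 14 weeks, a log2 fold change of 1.93 ± 0.38 (SE; edgeR adjusted p = 0.018). Nfu_g_1_022937, a gene of 432 bases, lost nearly all of its reads. It had 241 counts over the 5 libraries at 5 weeks and 3 at 14 weeks, where 2 libraries had 0 counts. That is a ratio of 83.9 with an exact 95% interval for counting error of 28.4 to 409.5. Its mean was 2.38 ± 1.84 CPM at 5 weeks, 2.71 ± 2.29 at 7 weeks and 0.185 ± 0.163 at 10 weeks. The edgeR adjusted p for 14 against 5 weeks was 0.0041, and it also fell between 7 and 10 weeks, by 3.78 on the log2 scale (edgeR adjusted p = 0.0075). Nfu_g_1_014156 fell by 3.60 ± 0.77 (SE) on the log2 scale (edgeR adjusted p = 0.027). Its 5-week mean of 3.55 ± 4.78 CPM came largely from 5-week replicate 4, at 11.7 CPM, and every 14-week library lay between 0.259 and 0.313 CPM. Without 5-week replicate 4, the log2 fold change of Nfu_g_1_014156 was -2.33 (edgeR adjusted p = 0.076), that of Nfu_g_1_011849 was 1.83 (adjusted p = 0.075) and that of Nfu_g_1_019685 was 1.84 (adjusted p = 0.055). The call of Nfu_g_1_011849 was also lost without 14-week replicate 1 (adjusted p = 0.069), replicate 4 (0.078) or replicate 5 (0.055). Without the 3 libraries of lowest correlation its log2 fold change was 1.69 (edgeR adjusted p = 0.083). By limma-voom the log2 fold change of Nfu_g_1_014156 was -2.51 (adjusted p = 0.15), and by edgeR without the 3 libraries of lowest correlation, chosen after seeing the data, it was -1.33 (adjusted p = 0.15). Its call was also lost without 14-week replicate 1 (adjusted p = 0.073), replicate 3 (0.061) or replicate 4 (0.075).

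**Figure D2:**
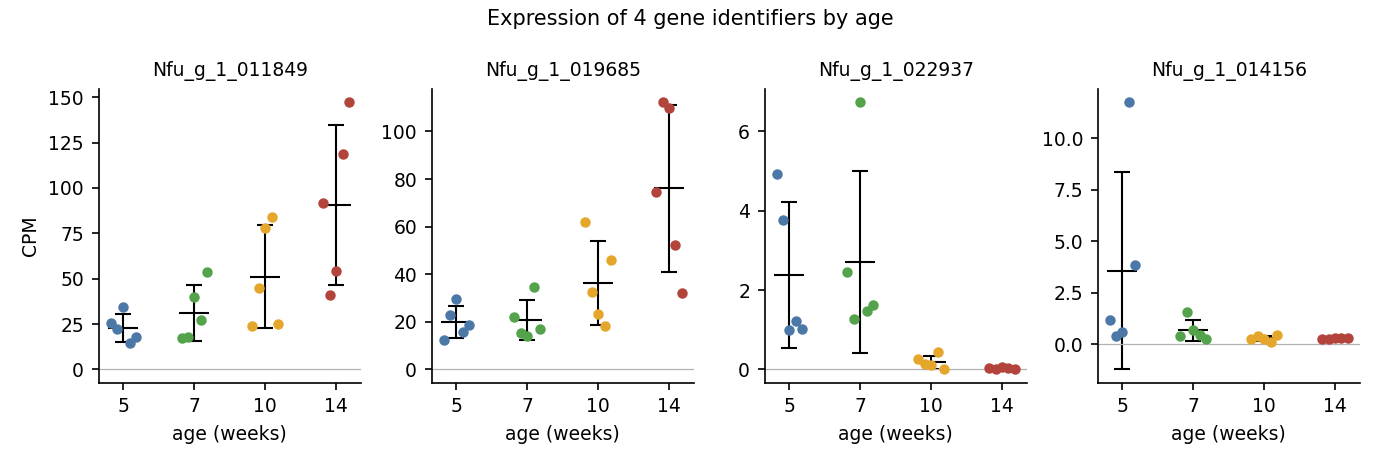
CPM of 4 gene identifiers against age in weeks, on separate linear axes. Points are single libraries, and the black lines give the mean and SD of the 5 libraries of an age. The rising pair reaches means of 90.6 and 76.2 CPM at 14 weeks, and Nfu_g_1_022937 falls to 0.185 CPM at 10 weeks.

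The size of the list for 14 against 5 weeks depended on the fit and on single libraries. With only these 2 ages in the fit edgeR called 92 genes higher and 124 lower, and DESeq2 on all libraries called 466 higher and 707 lower. It held 270 genes without 5-week replicate 1, 104 without 5-week replicate 4, 1197 without 7-week replicate 3, 315 without 7-week replicate 4, 299 without 10-week replicate 1, and 90, 117, 82 and 227 without 14-week replicates 1, 3, 4 and 5. Of the 482 genes, 66 were called the same way whichever library was left out, 20 higher and 46 lower. Without the 3 libraries of lowest correlation, a choice made after seeing the data, 439 genes were higher and 765 lower.

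In the fit of all 20 libraries, the interval from 7 to 10 weeks had the most calls of the 3 intervals between successive ages. That order was not kept in fits of only the 2 ages compared, which called 60 genes between 7 and 10 weeks, 72 between 10 and 14 weeks and 0 between 5 and 7 weeks (edgeR; 1388 genes at an unadjusted p below 0.05 in the last; DESeq2 on all libraries called 304 there). Between 5 and 7 weeks 3 genes rose and 3 fell in the fit of all libraries, with full separation in each of the 6, and 1 of them changed more than 2-fold. At an unadjusted p below 0.05 there were 2312 genes. The count depended on 7-week replicate 3, without which 113 genes were higher and 138 lower, and on 7-week replicate 5, without which it was 13. With the 3 libraries of lowest correlation left out, 30 were higher and 63 lower.

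Between 7 and 10 weeks 222 genes rose and 313 fell (edgeR, adjusted p below 0.05). The median absolute log2 fold change was 0.61 in both directions. Changes beyond 4-fold were seen in 1 rising and 30 falling genes, and 427 of the 535 genes separated all libraries of 10 weeks from all libraries of 7 weeks. Most genes that changed from 5 to 14 weeks moved the same way here. The 7- and 10-week libraries are not those compared at 14 and 5 weeks, but all 20 libraries share the fit and its dispersions, so both lists of calls depend on all of them. Of the 195 genes higher at 14 than at 5 weeks, 179 had a positive log2 fold change between 7 and 10 weeks (median 0.37), and 41 were called higher, where independent lists would share 2.22. Of the 287 lower genes, 246 had a negative log2 fold change (median -0.35) and 60 were called lower, where independent lists would share 4.61. No gene was called in opposite directions. In separate fits of the libraries of 5 and 14 weeks and of those of 7 and 10 weeks, 85 of 91 higher and 119 of 124 lower genes had the same sign, and 2 higher and 6 lower genes were called in both, where independent lists would share 0.112 and 0.245. These comparisons were added after seeing the data. The same-sign share of 88.2% did not stand apart from other splits of the 7- and 10-week libraries, since 11 of 100 splits (the real one included) gave a share as far from even. The number of shared calls did stand apart. Only 1 of 100 splits, the real one, gave as many as the 41 and 60 together, and the highest other gave 26. Other splits also called fewer genes between 7 and 10 weeks (highest 114, against 535), which leaves fewer to share. The shared calls are therefore not evidence separate from the number of calls. The count of 535 fell to 184 without 7-week replicate 2, to 175 without 7-week replicate 4, and to 181, 132, 91 and 208 without 10-week replicates 1, 2, 3 and 4. With the 3 libraries of lowest correlation left out, 501 genes were higher and 563 lower, and with only these 2 ages in the fit 23 were higher and 37 lower. The excess of falling genes was not kept with 1 surrogate variable (603 higher, 563 lower) or by limma-voom (230 higher, 228 lower).

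**Figure D3:**
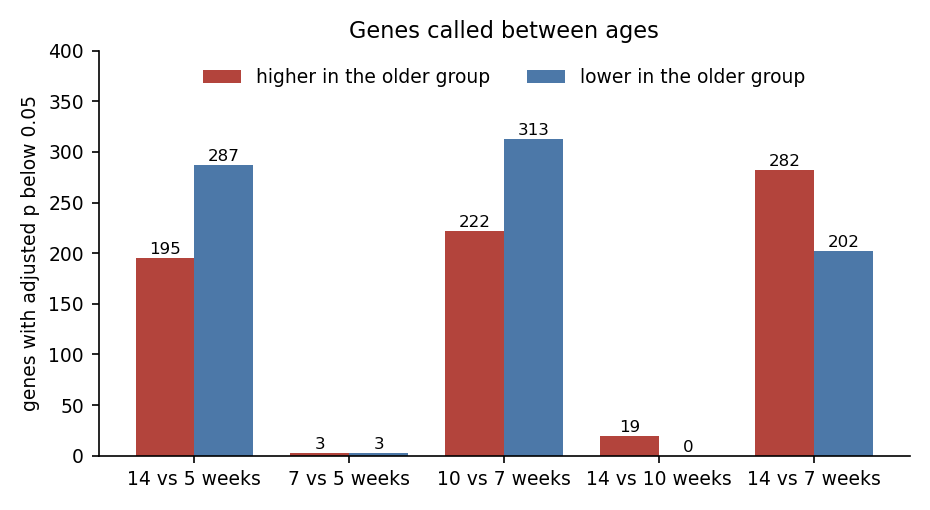
Number of genes with an edgeR adjusted p below 0.05 in 5 comparisons of ages, with genes higher in the older group in red and genes lower in blue. The bars for 10 against 7 weeks stand at 222 and 313 genes, those for 7 against 5 weeks at 3 and 3, and those for 14 against 10 weeks at 19 and 0.

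Between 10 and 14 weeks 19 genes were higher and 0 lower by edgeR, with 805 genes higher and 379 lower at an unadjusted p below 0.05. DESeq2 called 84 higher and 10 lower, edgeR with only these 2 ages in the fit 65 higher and 7 lower, and limma-voom called 0 in either direction, with 1211 genes at an unadjusted p below 0.05. The 19 genes had a median log2 fold change of 3.92, larger than that of the longer lists of the other comparisons, and 14 of them lay beyond 4-fold. More genes lay beyond 4-fold in some of those lists, with 33 falls between 5 and 14 weeks and 30 between 7 and 10 weeks. In each of the 19 genes, which were chosen for differing between these libraries, every library of 14 weeks exceeded every library of 10 weeks. Among all tested genes, called or not, 258 lay fully above and 256 fully below. The 19 genes did not rise steadily over age. Their geometric mean was 0.572 to 0.678 CPM in the 10-week libraries and 6.06 to 6.72 CPM in the 14-week libraries. At 5 weeks it was 4.37 to 5.79 CPM in 4 libraries and 0.744 CPM in replicate 4. At 7 weeks it was 5.19, 3.61 and 4.50 CPM in replicates 3, 4 and 5, and 1.62 and 0.698 CPM in replicates 1 and 2. The count of 19 changed by over 1.5 times without 16 of the 20 libraries. It was 3 without 10-week replicate 1, 2, 3 or 5 and 8 without replicate 4. It was 5 without 14-week replicate 1, 2 or 3 and 4 without replicate 4. It was 6 without 5-week replicate 1 or 3, 42 without 5-week replicate 4, and 31, 30, 36 and 5 without 7-week replicates 1, 2, 3 and 4.

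**Figure D4:**
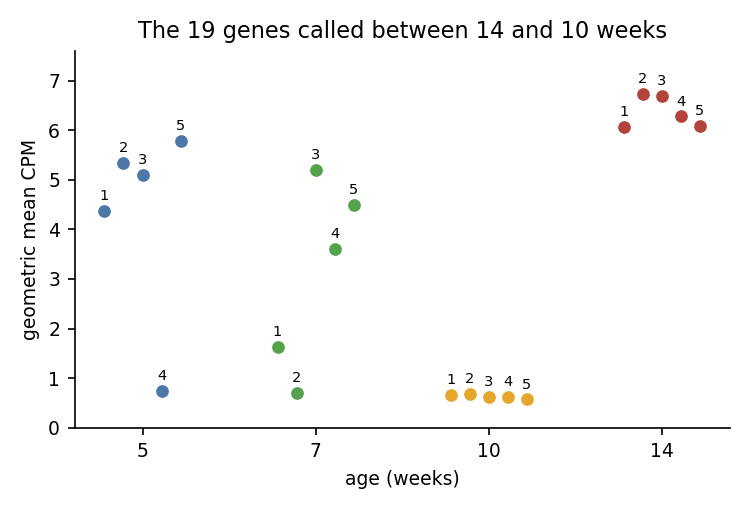
Geometric mean CPM of the 19 genes called between 14 and 10 weeks, on a linear axis, against age in weeks. Each point is a library marked with its replicate number. The 10-week libraries lie at 0.572 to 0.678 CPM and the 14-week libraries at 6.06 to 6.72 CPM, and the 7-week libraries range from 0.698 to 5.19 CPM.

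Between 7 and 14 weeks 282 genes rose and 202 fell (edgeR, adjusted p below 0.05). The median absolute log2 fold change was 0.76 among rising and 0.54 among falling genes, and 368 of the 484 genes showed full separation. Changes beyond 2-fold were seen in 90 rising and 22 falling genes. The count of 484 was 133, 766 and 232 without 7-week replicates 2, 3 and 4, 320 without 10-week replicate 2, and 200, 235 and 198 without 14-week replicates 1, 3 and 4. With the 3 libraries of lowest correlation left out, 995 genes were higher and 919 lower, and with only these 2 ages in the fit 58 were higher and 21 lower.

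Over the 4 ages together, 1400 genes differed (edgeR F-test, adjusted p below 0.05), 7.19% of those tested. Most of them did not move in 1 direction throughout. Group means rose at every step in 85 genes and fell at every step in 129, together 15.3% of the 1400, while 10.3% of all tested genes had such an order. The highest mean was at 5 weeks in 541 genes and the lowest at 10 weeks in 542. A linear trend was called in 981 genes, 395 rising by a median of 0.077 and 586 falling by a median of 0.082 on the log2 scale per week, and 702 of these were among the 1400. Over 7, 10 and 14 weeks alone the trend was called in 134 rising and 44 falling genes, so the larger number of falling genes depended on the 5-week libraries. Nfu_g_1_011849 rose by 0.22 ± 0.041 (SE) and Nfu_g_1_019685 by 0.23 ± 0.036 per week, with edgeR adjusted p-values of 0.0092 and 0.0029. The count of 1400 was 2624 without 7-week replicate 3, 912 without 7-week replicate 4, 826, 774 and 720 without 10-week replicates 1, 2 and 3, and 857 and 908 without 14-week replicates 1 and 3. The count of 981 was 617 and 486 without 5-week replicates 1 and 4, 606 without 7-week replicate 2, and 446, 600 and 272 without 14-week replicates 1, 3 and 4.

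By Pearson's r, no relation beyond the other splits was found between the changes from 5 to 7 weeks and those from 10 to 14 weeks. Across the 19474 genes, which are not independent replicates, the log2 fold changes of both intervals had a Pearson r of -0.08 and a Spearman rho of -0.22, and 42.2% of genes had the same sign. In 100 splits of the 10- and 14-week libraries, the real one included, a share of 0.37 gave an r as large. The Spearman rho and the same-sign share were not set against these splits. On differences of mean log2 CPM, a statistic added after seeing the data, r was -0.14 (exact permutation p = 0.12 over 252 assignments). Without 5-week replicate 4 the r of the edgeR changes was -0.18, and the permutation p on mean log2 CPM was 0.032. An opposite course is therefore not excluded, but it was not seen among genes with a mean CPM of at least 10. There r was -0.0017, and a share of 0.99 of the splits gave an r as large. Gene length was weakly related to the change between 14 and 5 weeks across genes (Spearman rho = 0.08), and a share of 0.40 of 100 splits of the 5- and 14-week libraries gave a rho as large. Among genes with a mean CPM of at least 10 that rho was 0.16, and a share of 0.37 of the splits gave one as large.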

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

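The tests of other explanations below were chosen only after the results they concern had been seen, apart from the splits of libraries, and the limits were written before the tested value or related values had been seen only for the splits, the length of the 19 genes and their rho with library totals, and the top 10 genes in 5-week replicate 5.

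Calling as many genes as the real grouping was rare when the libraries were split anew. Of 100 splits, the real one included, 1 gave as many as 482 genes for 14 against 5 weeks (highest other 10), 1 as many as 535 for 10 against 7 weeks (highest other 114), 1 as many as 19 for 14 against 10 weeks (highest other 1) and 1 as many as 484 for 14 against 7 weeks (highest other 18). For 7 against 5 weeks 4 splits gave as many as 6 genes, and the highest gave 241. Of 100 reassignments of the 20 libraries, 1 gave as many as 1400 genes for the 4 ages (highest other 180) and 1 as many as 981 for the linear trend (highest other 156). Such splits cannot tell age from another difference that follows it, such as the order of the running numbers in the sample titles.

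The 19 genes called between 14 and 10 weeks also separated libraries of the same age at 5 and 7 weeks. Over the 5- and 7-week libraries, their mean pairwise correlation within ages was 0.807, against a highest value of 0.393 in 10000 sets matched on expression. That correlation restates the pattern, so a batch that the labels do not give and a shared biological state both stay open. The running numbers in the sample titles follow age, except that 7-week replicates 4 and 5 come after the 10-week libraries. Those replicates, at geometric means of 3.61 and 4.50 CPM, lay above every 10-week library. Of the 7-week libraries numbered earlier, replicate 3 was high (5.19 CPM) and replicate 2 low (0.698 CPM). An effect of that order was not told from age. The number of reads sampled was an unlikely cause, since the correlation was 0.788 (highest of matched sets 0.380) and all 19 genes stayed separated between 14 and 10 weeks after every library was thinned to the smallest total; the median absolute Spearman rho with the total, 0.409, lay between the limits written for it. Gene length was an unlikely cause, since their median length of 1974 bases lay at the 59.0th percentile of matched sets.

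In 7-week replicate 3, 1864 genes with a mean CPM of at least 8 lay more than 2-fold below the other libraries of its age. Gene length may explain little of it, since 88.8% of these genes stayed as low after a smooth trend on length was removed. The library's deviation had a Spearman rho of -0.31 with gene length, the most negative of all libraries, so some effect of length is not excluded. Its total of 21.6 M counts (M, mega) lay within the range of the other 7-week libraries, so depth was an unlikely cause. A share of tissue that differs between dissections could be the cause: the genes were correlated within the other ages (mean pairwise correlation 0.487, highest of matched sets 0.0348), with 1000 matched sets run instead of the 10000 written down. These genes were low mainly in 5-week replicate 5 (median log2 deviation -0.82), itself a library that stood apart, and 14-week replicate 5 (-0.43). In the other 13 the median deviation was -0.06 to 0.15. Without 5-week replicate 5 the correlation was 0.276 (highest of matched sets 0.0070). Genes low together in 1 library can correlate under any difference these libraries share. A tissue share was therefore not told from a shared state of the cells or from another such difference.

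In 5-week replicate 5, 79.7% of 1573 genes nearly silent in the other 19 libraries had a read, against 14.3% to 26.9% in each of those libraries for its own set of 1452 to 1475 genes nearly silent in the rest. A background of reads over gene bodies, such as genomic DNA or unspliced RNA, could be the cause. Counts in these genes rose with gene length (Spearman rho 0.448, against 0.022 to 0.106 in the other 19 libraries). Longer genes give more reads from any source of RNA, so the rho does not tell such a background from other RNA. Its total of 12.004 M was the lowest of all libraries, so depth was an unlikely cause. RNA from a tissue that adds a few abundant transcripts may be less likely, since the 10 genes with the most reads held 6.40% of them. RNA from a tissue that expresses many of these genes was not excluded.

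Further values stood apart from the other 4 libraries of an age, in 10 of 60 groups tested over 15 measures, where chance gives about 1 in 20. The median rho with other libraries was 0.925 in 7-week replicate 3 (others 0.9748 to 0.986). Its distance to the centroid was 114 (others 42.5 to 61.9). Nfu_g_1_022937 was at 6.73 CPM in that library (others 1.27 to 2.46). Reads in nearly silent genes were 892 RPM in 5-week replicate 5 (others 13.7 to 33.8). In that library 674 genes with a mean CPM of at least 8 lay more than 2-fold below the group (others 42 to 165). In 7-week replicate 2, 87 genes lay more than 8-fold above the group (others 1 to 17). In 10-week replicate 4 there were 17 such genes (others 3 to 7). In 5-week replicate 4 the top 10 genes held 5.01% of counts (others 3.63% to 3.98%). The geometric mean of the 19 genes was 0.744 CPM in that library (others 4.37 to 5.79).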

How the results depend on the processing

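Leaving out the 3 libraries of lowest correlation, RPKM scaled by own totals and correlations on mean log2 CPM were chosen only after the results were seen; the other alternatives were planned. Pairs of counts below give genes higher, then lower, in the older group, and where a count moved the cause was not tested.

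For 14 against 5 weeks (195 and 287), DESeq2 gave 466 and 707, 1 surrogate variable 406 and 540, only the 2 ages 92 and 124, and leaving out the 3 libraries 439 and 765. The deposited RPKM, whose totals rotate between libraries, gave 14 and 13 with 1 added, 5 and 4 with 0.1 added, and 1 and 0 with no filter (limma-trend; 2063 genes at an unadjusted p below 0.05; edgeR 3621).

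For 7 against 5 weeks (3 and 3), the filter of at least 1 CPM in 5 libraries gave 6 and 8, DESeq2 105 and 199, 1 surrogate variable 46 and 71, leaving out the 3 libraries 30 and 63, and own-total RPKM 3 and 8. With only the 2 ages edgeR gave 0 and 0 (1388 at an unadjusted p below 0.05). The deposited RPKM gave 0 and 0 by limma-trend in each of 3 forms (3412, 3328 and 3670 at an unadjusted p below 0.05), where DESeq2 gave 105 and 199.

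For 10 against 7 weeks (222 and 313), no filter gave 140 higher, DESeq2 453 and 767, 1 surrogate variable 603 and 563, only the 2 ages 23 and 37, and leaving out the 3 libraries 501 and 563. The deposited RPKM gave 0 and 19 with 1 added, 0 and 24 with 0.1 added, and 0 and 11 with no filter (limma-trend; 2235, 2175 and 2441 at an unadjusted p below 0.05; edgeR 222 higher).

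For 14 against 10 weeks (19 and 0), DESeq2 gave 84 and 10, limma-voom 0 and 0 (1211 at an unadjusted p below 0.05), 1 surrogate variable 24 and 3, only the 2 ages 65 and 7, leaving out the 3 libraries 81 and 22, and own-total RPKM 10 higher. The deposited RPKM gave 30 higher with 0.1 added and 5 higher with no filter.

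For 14 against 7 weeks (282 and 202), no filter gave 183 higher, DESeq2 564 and 501, 1 surrogate variable 982 and 716, only the 2 ages 58 and 21, leaving out the 3 libraries 995 and 919, and own-total RPKM 130 lower. The deposited RPKM gave 7 and 6 with 1 added, 7 and 8 with 0.1 added, and 5 and 5 with no filter.

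For the 4 ages (1400), DESeq2 gave 2785, 1 surrogate variable 2593 and leaving out the 3 libraries 2956. The deposited RPKM gave 103, 93 and 40. For the linear trend (395 rising and 586 falling), DESeq2 gave 611 rising, 1 surrogate variable 775 and 883, ages 7, 10 and 14 weeks alone 134 and 44, leaving out the 3 libraries 743 rising, and own-total RPKM 375 falling. The deposited RPKM gave 17 and 20 with 1 added, 15 and 25 with 0.1 added, and 8 and 11 with no filter.

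Leaving out each library in turn, 14 against 5 weeks ran from 30 to 430 higher and 50 to 767 lower, 7 against 5 weeks from 1 to 113 and 2 to 138, and 10 against 7 weeks from 30 to 303 and 61 to 434. For 14 against 10 weeks the ranges were 3 to 41 and 0 to 2, and for 14 against 7 weeks 77 to 478 and 56 to 288. The 4 ages ran from 720 to 2624, rising genes from 121 to 556 and falling genes from 151 to 850.

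The Spearman rho of PC2 with age (0.51) was 0.45 with all tested genes (permutation adjusted p = 0.099) and 0.28 with 2000 genes (adjusted p = 0.47), and ran from 0.069 to 0.59 without single libraries, with an adjusted p above 0.05 in 17 of 20. The components were computed anew in each of these settings, so PC2 need not be the same axis. Pearson's r of PC2 with all tested genes was 0.50 (permutation adjusted p = 0.036). The rho of PC1 ran from 0.039 to 0.33. In every setting each component was turned so that its Pearson r with age was positive. The sign of these correlations was therefore largely set beforehand. The r between 7 against 5 and 14 against 10 weeks (-0.08) ran from -0.18 without 5-week replicate 4 (permutation p = 0.032, below the threshold only there) to 0.0042 without 7-week replicate 2, and was 0.00084 without 5-week replicate 5, so its sign reversed without either of the latter. The p without single libraries rests on differences of mean log2 CPM, which gave -0.14 (exact permutation p = 0.12) with all libraries; for gene length they gave 0.075 (exact permutation p = 0.44). Without single libraries the rho with gene length ran from 0.052 to 0.116 and the difference in spread from -22.1 to -3.86. Among genes with a mean CPM of at least 10 the rho with gene length was 0.16 (share of splits as large 0.37).

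The log2 fold change between 14 and 5 weeks ran without single libraries from 1.73 to 2.17 for Nfu_g_1_011849, from 1.75 to 2.13 for Nfu_g_1_019685, from -6.36 to -5.67 for Nfu_g_1_022937 and from -3.89 to -2.33 for Nfu_g_1_014156. For Nfu_g_1_014156 it was -2.51 by limma-voom and -1.33 by edgeR without the 3 libraries (adjusted p = 0.15 in both). Over all settings their adjusted p stayed below 0.05 in 25 of 33, 31 of 33, 32 of 33 and 21 of 31. Nfu_g_1_014156 has no value with at least 1 CPM in 5 libraries or with only the 2 ages, where it was not tested. The alternatives for gene lists were not run, since no list matched an identifier.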

Other observations

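The comparisons in this part were chosen only after the results were seen.

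A comparison of 10 against 5 weeks, not planned, called 414 genes higher and 749 lower (edgeR, adjusted p below 0.05), more than any planned comparison of 2 ages, and 791 of the 1163 genes were fully separated. Of the 749, 60 had a mean below 1 CPM. It was run only in the fit of all 20 libraries, without the alternatives, the leaving out of single libraries or the splits.

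Of 207 genes more than 8-fold above the group in 5-week replicate 4 and 87 in 7-week replicate 2, 75 were the same, where independent lists would share 0.925. The next highest pair of libraries shared 21. Of the 287 genes lower at 14 than at 5 weeks, 23 were among the 207, which came from 19474 tested genes. Both lists rest partly on 5-week replicate 4, without which 74 genes were called lower.

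Nfu_g_1_002728 was singled out after its values were seen. It was at 716, 1727, 1342 and 790 CPM in 14-week replicates 1 to 4, at 4.44 CPM in replicate 5, at 155 CPM in 7-week replicate 1 and at 0.29995 to 9.44 CPM in all other libraries.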
